A study of Gallus gallus with 23 samples.

How the data were processed

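Gene expression was measured in the livers of 23 broiler cockerels on 2-colour spotted cDNA arrays with 19200 spots in 48 blocks. Of 72 birds housed 3 to a pen in 2 rooms, each of the 23 had received a pump releasing 1.0 microlitre per hour at 29 days of age. RNA of each bird (20 micrograms, dye Alexa Fluor 555) was hybridised against a common pool of RNA from 6 control birds (dye Alexa Fluor 647), 1 array per bird. The values deposited by the authors were taken as log2 ratios of the channels. The labels state neither the log base, the numerator, the background correction, the normalization nor a spot filter; base 2 was assumed from the range of the values (-3.86 to 4.05). Array medians lay between -0.05 and 0.03, and 28.5 to 53.5% of the spots were blank on each array. No slide, scan date or batch is given, so a batch effect could not be examined.

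On 6 arrays, values sat against the wrong spots. Each array was compared, across spots, with the mean of the others after block and row effects had been removed. On 17 arrays the correlation was 0.277 to 0.609. On 4 arrays (CS replicate 3, T3 replicate 3, CS+T3 replicate 1 and VC replicate 4) it was -0.042 to 0.012, but it rose to 0.319 to 0.5 when the values were moved 1 to 14 spots later in printing order, over most of the array. The blank spots of these arrays matched those of the other arrays in place (r of 0.792 to 0.838) and not at the lag of the values (0.053 to 0.205). CS+T3 replicate 2 and T3 replicate 1 were shifted over part of their spots. A dynamic-programming search chose nondecreasing lags of up to 40 spots, and an array was realigned if 1 of its parts had at least 1000 spots at a lag and r of at least 0.25 there. Parts with r under 0.1, blocks in which the lag changed, and spots blank in the deposited column were left missing, and 6348 to 10816 values remained on the 6 arrays. In a self-test on the 17 unshifted arrays with 3 spots removed, the search gave the right lag for 94.8% or more of the spots (median 99.7%). There the lag grew by 1 spot at a time to at most 3, and blanks moved with the values. Larger jumps, such as from a lag of 2 to 20 spots on T3 replicate 1, and blanks that stay in place were not covered. The decision to realign used no group, but it was made after the data were examined. Feature counts are therefore also given with the values as deposited and without the 4 or the 6 arrays, and the effect on lists and named genes as counts.

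Spots were named from the platform annotation: 10601 spots had 1 gene symbol, 0 had several and 8599 had none; 10455 of the named spots were matched through their Entrez ID and 146 were not, and no symbol needed updating. Names were checked by comparing spots of the same gene, whose correlation was highest in place (median r of 0.389). Spots of a gene were averaged and unnamed spots were tested on their own. Among 65 gene and comparison pairs of named genes with several spots, the spots had opposite signs in 10, 6 of them of DIO1 (30 spots) and the others of ATP5B, CD74, CEBPB and AKR1B10. HSD11B1, NR3C1, DIO3, ME1 and TSC22D3 were not measured under these symbols, while HSD11B1B was measured and lies outside the naming rule.

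Features with at least 3 values in each group were fitted with limma 3.58.1 in R 4.3.3 (group means over all 23 arrays, empirical Bayes, Benjamini-Hochberg threshold 0.05) for 7 comparisons, the last being the difference of the T3 effect with and without CS. No array normalization was added. Gene lists (25, fixed before the data were examined) were tested with limma's competitive test at a preset correlation of 0.01, and again with a correlation estimated from the residuals. In 3 cases an old synonym in a list pointed to another gene, and these matches were dropped after the data were examined. The lists cover fatty acid synthesis, lipid droplets and lipoproteins, fatty acid oxidation and ketone bodies, cholesterol synthesis, bile acid synthesis and sterol export, glycolysis, gluconeogenesis and glycogen, the glucocorticoid response, thyroid hormone response and metabolism, the growth hormone and IGF axis, oxidative phosphorylation, the tricarboxylic acid cycle, amino acid catabolism and nitrogen disposal, plasma and acute-phase proteins, xenobiotic and steroid metabolism, endoplasmic reticulum folding and heat shock, ribosomal proteins, the proteasome, the cell cycle, and markers of leukocytes, erythrocytes, stellate cells and matrix, endothelium, bile duct, and pancreas, muscle and adipose carry-over. List means per bird were compared between groups with 2-sided exact permutation tests, which were not run for the interaction.

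Genes were named by a rule fixed before the data were examined. Against VC, these were the 8 genes with the largest log2 fold change each way among those past the test, with a value on every array of both groups and every treated array on the same side of the control mean. The rule took 5 each way for CS against T3 and for the interaction (there without the condition on single arrays), and 3 each way for the remaining comparisons. It added the up to 4 members with the smallest adjusted p of each list with a call and 6 genes of receptors and enzymes, of which THRA, THRB and DIO1 were measured.

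Alternatives were other array scalings (median, quantile, equal spread), other filters, other ways to combine spots, only the compared groups in the fit, array weights, robust variances, a replicate block, and leaving out each array. Other splits of the samples (100 per comparison, the real one included) were counted; for the interaction, whole columns of residuals from the additive model were reordered, with missing values kept with their array and the filter of the real fit applied to all features (7782 to 9347 tested). A first version also blanked the values missing at the original array, and a second kept the features of the real fit with at least 2 values per group. Both were corrected after their results were seen; the count of 8 was not reached by any reordering in the 3 versions. Shared controls were simulated by shuffling whole residual columns 100 times. The fit was tested on simulated data with 200 changed features, and the list test on a list shifted by 0.3, the only list it called. The simulated noise was independent between features. It therefore could not show false calls from genes that vary together, whose estimated residual correlation reached 0.219 in the plasma and acute-phase list. Figures and alignment used Python with numpy, pandas and matplotlib.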

Results

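Hepatic gene expression was measured in 23 broiler cockerels whose hormones had been set by an implanted pump for 6 days from 29 days of age. Birds received vehicle (VC, 6 arrays), corticosterone (CS, the main glucocorticoid of birds, 600 micrograms per kg per day, 6 arrays), triiodothyronine (T3, the active thyroid hormone, 192 micrograms per kg per day, 6 arrays) or both hormones (CS+T3, 5 arrays). Each array compared the liver RNA of 1 bird with a reference pool of RNA from 6 control birds, so the values are log2 ratios to that pool. Arrays held values for 8925 to 13721 of 19200 spots, and 9250 features (4836 named genes and 4414 spots without a gene name) had at least 3 values in every group and were tested. The number of arrays limits the precision, and the median residual SD of a feature was 0.221 on the log2 scale.

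The deposited table does not state which channel is the numerator. Positive values were taken to mean higher in the bird than in the pool, an assumption that the planned checks did not settle. Among 30 spots of genes of blood, muscle and other carry-over tissues, the value farthest from the median was positive in 17 (56.7%, exact 95% interval 37.4 to 74.5%), against 59.6% of all 12199 spots. It was positive in 5 of 5 such spots where it lay at least 1 from the median, against 62.3% of all spots, a subset chosen after the data were examined. The target genes fixed beforehand did not settle it. Between T3 and VC, THRSP differed by 0.86 (SE 0.29, adjusted p = 0.959) and DIO1 by -0.05 (SE 0.07). Between CS and VC, FKBP5 differed by 0.27 (SE 0.12, adjusted p = 0.22) and TAT by -0.37 (SE 0.14, adjusted p = 0.156). Outside the comparisons fixed for them, between CS+T3 and VC, THRSP differed by 1.45 (SE 0.30, adjusted p = 0.102), FKBP5 by 0.47 (SE 0.12, adjusted p = 0.349), TAT by 0.47 (SE 0.15, adjusted p = 0.662) and DIO1 by 0.003 (SE 0.08). THRSP passed between CS+T3 and CS (1.65, SE 0.32, adjusted p = 0.00801) and between CS and T3 (-1.06, SE 0.30, adjusted p = 0.0357). The signs of THRSP, FKBP5 and TAT there are those of the assumed direction, which remains an assumption. If the numerator were the pool, every direction given here would turn round.

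The first comparison, CS against VC, asks what corticosterone alone did to the liver. Genes for proteins that hepatocytes secrete into plasma fell together. F2, which encodes prothrombin, fell by 1.05 (SE 0.13, n = 6 and 6, adjusted p = 0.000239), from a log2 ratio of -0.03 ± 0.21 (SD) in VC to -1.08 ± 0.26 in CS. PLG, the plasminogen gene, fell by 1.23 (SE 0.18), AMBP, which encodes a precursor of alpha-1-microglobulin and bikunin, by 1.64 (SE 0.27, n = 5 and 6) and GC, the vitamin D-binding protein, by 1.20 (SE 0.20). GPT2, an alanine aminotransferase that moves amino groups between amino acids and keto acids, rose by 0.82 (SE 0.16, n = 6 and 6, adjusted p = 0.00511).

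Of the 30 measured members of the plasma and acute-phase list, 17 fell and 13 did not pass the test (21 fell adjusted over the list alone), with a mean log2 fold change of -0.80 and adjusted p = 1.61e-24 (adjusted p = 0.000239 with an estimated correlation). The mean of the list was below the VC mean in 6 of 6 CS arrays (exact permutation p = 0.00216, adjusted 0.0386 over 25 lists, the smallest p this design allows). The list of xenobiotic and steroid metabolism was lower (mean log2 fold change -0.202, median -0.078, adjusted p = 0.00869, and adjusted p = 0.0454 with an estimated correlation). Of its 21 members 1 was past the test over all features and 5 adjusted over the list alone. UGT2A1, a glucuronosyltransferase, fell by 0.66 (SE 0.12, n = 4 and 6). CYP2AC1 differed by -0.59 (SE 0.17), CYP2D6 by -0.47 (SE 0.15) and GSTK1 by -0.36 (SE 0.12). Ribosomal protein genes had a mean of -0.171 (adjusted p = 0.00124; adjusted p = 0.183 with an estimated correlation), and 3 of 42 fell (5 fell and 1 rose adjusted over the list alone): RPS24 by 0.54 (SE 0.13), RPL11 by 0.82 (SE 0.22) and RPS12 by 0.55 (SE 0.15). RPL31 stood at -0.52 (SE 0.15, adjusted p = 0.0526). Beside these lists, erythrocyte markers had a mean of 0.268 (adjusted p = 0.131), leukocyte markers of -0.141 (adjusted p = 0.147) and bile duct markers of -0.161 (adjusted p = 0.511) by the competitive test. Per bird, the means of erythrocyte markers (0.262) and bile duct markers (-0.173) did pass (each adjusted p = 0.0386 over 25 lists, 6 of 6 CS arrays beyond the VC mean), and that of leukocyte markers did not (-0.150, adjusted p = 0.0961). The bile duct fall rested on 1 of 8 members, TM4SF4 (-1.3). Without it the mean log2 fold change of the list was 0.001, and the median of all members was 0.005.

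Among genes with a value on every array of both groups, the largest falls by the naming rule were those of EPB41L5 (2.05, SE 0.38), MME, the membrane metalloendopeptidase neprilysin (log2 fold change -1.71, SE 0.31), and PSPH, the last enzyme of serine synthesis (log2 fold change -1.67, SE 0.29). AP1M1 (-1.56), SPIA4 (-1.30), the bile duct marker TM4SF4 (-1.30) and 2 members of the plasma protein list also fell, SERPIND1, the thrombin inhibitor heparin cofactor II (-1.33), and complement C3 (-1.31). Among genes with a value on every array of both groups, the largest rises by the naming rule were those of NTRK2, the receptor of brain-derived neurotrophic factor (1.13, SE 0.25), TMEM185B (0.96), SIRT2, a NAD-dependent deacetylase (0.85), RNF152 (0.83), GPT2 (0.82), TBC1D9B (0.77), RNF126 (0.76) and GNL2 (0.72). The thyroid hormone receptor genes THRA (0.09, SE 0.14) and THRB (0.06, SE 0.13) and DIO1, the type 1 deiodinase (0.25, SE 0.07, adjusted p = 0.0526), did not pass. In all, 377 features passed, 91 up and 286 down, of which 43 and 127 were named genes, and 1813 had an unadjusted p under 0.05. With the values as deposited 72 passed (2 up, 70 down), without the 4 arrays misplaced over most of their spots 188, and without all 6 arrays with a misplaced part 237. The count was 147 after quantile normalization, 220 without CS replicate 4, 248 without VC replicate 2 and 602 without CS replicate 5.

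T3 against VC asks the same of thyroid hormone alone. Genes of fatty acid synthesis had a higher mean in T3, with a mean log2 fold change of 0.142 (22 members, adjusted p = 0.0105, and adjusted p = 0.0862 with an estimated correlation). The median of the members was only 0.03, so the list did not rise evenly, and none of the 22 passed on its own. THRSP, a thyroid-responsive regulator of lipogenesis, stood at 0.81 ± 0.65 (SD, n = 6) in T3 and -0.04 ± 0.34 (n = 6) in VC. SLC25A1, the mitochondrial citrate carrier, differed by 0.59 (SE 0.19), ACSL1, an acyl-CoA synthetase, by 0.52 (SE 0.17) and ELOVL2, an elongase of polyunsaturated fatty acids, by 0.33 (SE 0.14). The mean of the list per bird was above the VC mean in 6 of 6 T3 arrays (exact permutation p = 0.039, adjusted 0.238 over 25 lists). DIO1 (-0.05, SE 0.07), THRA (0.08, SE 0.13) and THRB (-0.00, SE 0.13) did not pass. The list of thyroid hormone response and metabolism had a mean of 0.034 (adjusted p = 0.803 by the competitive test), and none of its 14 members passed. With limma 0 features passed, 440 had an unadjusted p under 0.05, and the smallest adjusted p was 0.959. The 440 are a smaller share of the 9250 features tested than the 0.05 that unchanged features would give. In simulated data with the same arrays, 45% of changes of 0.5 and 93% of changes of 1 on the log2 scale were recovered, so smaller changes were mostly not detectable here.

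CS+T3 against VC asks what both hormones did together. GPT2 rose by 1.10 (SE 0.18, n = 4 and 6, adjusted p = 0.00891). INTS6, a subunit of the Integrator complex, rose by 1.04 (SE 0.14, n = 5 and 5), TM2D3 by 1.41 (SE 0.19, n = 5 and 6) and C1QTNF7 by 2.11 (SE 0.39, n = 5 and 6). These were the named genes among 5 features past the test, all up, with 414 at an unadjusted p under 0.05. The 414 are a smaller share of the 9250 features tested than the 0.05 that unchanged features would give. INTS6 was named after its value was seen, and GPT2 both so and as a member of a list with a call. Oxidative phosphorylation genes rose as a list, with a mean of 0.215 over 34 members (adjusted p = 1.44e-07; adjusted p = 0.000263 with an estimated correlation). None of the members passed over all features and 3 did adjusted over the list alone. The per-bird mean of the list differed by 0.210 and did not pass (exact permutation p = 0.00433, adjusted 0.0541 over 25 lists). No other list passed per bird in this comparison. UQCRQ of complex III differed by 0.57 (SE 0.14), and NDUFA9 (1.08, SE 0.28), NDUFB6 (0.36, SE 0.10) and NDUFC2 (0.33, SE 0.11) are subunits of complex I.

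Fatty acid synthesis genes had a higher mean in CS+T3 than in VC (0.194, median 0.063, adjusted p = 0.00186, and adjusted p = 0.0411 with an estimated correlation). Of these genes 1 of 22 was up adjusted over the list alone. THRSP differed by 1.45 (SE 0.30, adjusted p = 0.102), SLC25A1 by 0.62 (SE 0.20), GPAM, which starts triglyceride synthesis, by 0.67 (SE 0.27) and ACLY, which makes cytosolic acetyl-CoA from citrate, by 0.39 (SE 0.15). Amino acid catabolism genes also had a higher mean (0.135, median 0.048, adjusted p = 0.00307, and adjusted p = 0.0411 with an estimated correlation). In this list 1 of 29 passed on its own (1 adjusted over the list alone): besides GPT2, TAT, which starts tyrosine breakdown, stood at 0.47 (SE 0.15), GOT2 at 0.34 (SE 0.16) and PAICS at 0.26 (SE 0.13). The glucocorticoid response list had a higher mean (0.130, median 0.024, adjusted p = 0.0333, and adjusted p = 0.267 with an estimated correlation). Of its 11 members 3 were up adjusted over the list alone. With corticosterone alone (CS against VC) the mean of this list was 0.021 (adjusted p = 0.981 by the competitive test), and 0 of 11 members passed. FKBP5, which binds the glucocorticoid receptor complex, stood at 0.47 (SE 0.12), TAT at 0.47 (SE 0.15) and CEBPB at 0.55 (SE 0.18), while DUSP1 stood at -0.18 (SE 0.12). Bile acid synthesis and sterol export was lower (mean -0.141, 6 members, adjusted p = 0.0333; adjusted p = 0.0411 with an estimated correlation). BAAT stood at -0.23 (SE 0.12), HSD3B7 at -0.23 (SE 0.12), AKR1D1 at -0.25 (SE 0.15) and ABCC2 at -0.18 (SE 0.11). Plasma protein genes were lower as a list (mean -0.290, adjusted p = 1.44e-07; adjusted p = 0.083 with an estimated correlation), 3 of 30 adjusted over the list alone, with TTR, the transthyretin gene, at -0.79 (SE 0.25), ITIH2 at -0.67 (SE 0.23), C8A at -0.63 (SE 0.20) and ITIH3 at -0.59 (SE 0.17). DIO1 (0.00, SE 0.08), THRA (0.00, SE 0.13) and THRB (-0.09, SE 0.14) did not pass. The count of 5 was 0 with the values as deposited, 3 without the 4 misplaced arrays, 1 without all 6, 31 with array weights, 3 after quantile normalization and 3 without CS+T3 replicate 1.

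**Figure D1:**
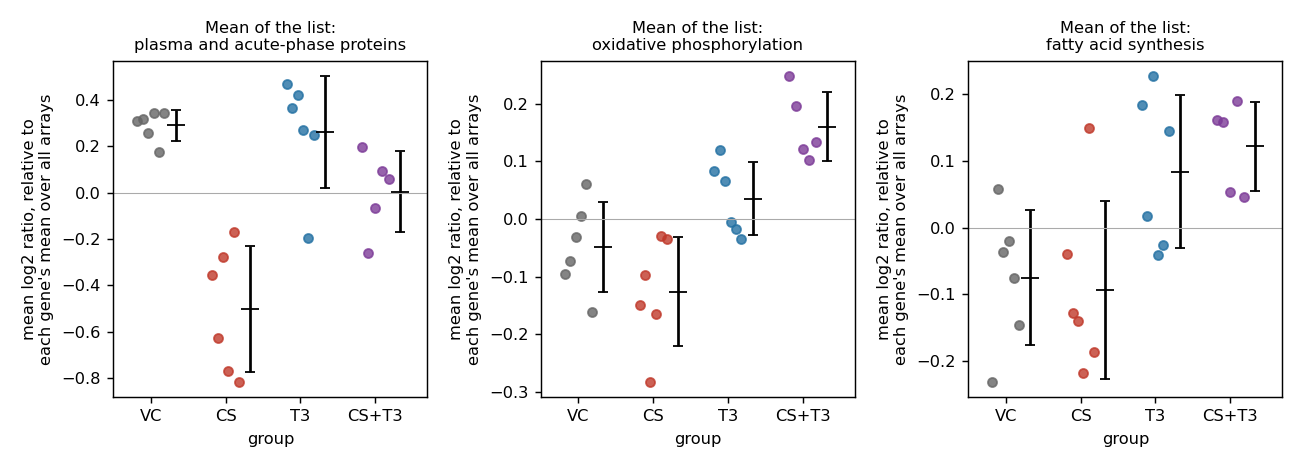
Mean of 3 gene lists on each array (y axis: mean log2 ratio of the members, each gene relative to its mean over all arrays) in the 4 groups (x axis); points are birds, and black bars are the mean and SD. The plasma protein mean lies below the VC mean in 6 of 6 CS arrays, and T3 replicate 5 stands at -0.20.

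CS against T3 sets the hormones against each other. GPT2 had the largest rise by the naming rule, higher in CS by 1.38 (SE 0.16, n = 6 and 6, adjusted p = 0.00018), at 1.02 ± 0.35 (SD) in CS and -0.36 ± 0.21 in T3. CRYBB2 (0.79), NCBP3 (0.79), NOL10 (0.78) and CCDC86 (0.74) were higher in CS too. Glycolysis genes had a lower mean in CS (-0.412, median -0.12, adjusted p = 0.00112, and adjusted p = 0.0107 with an estimated correlation). In this list 4 of 15 passed on their own (6 adjusted over the list alone): ENO1, an enolase, by a log2 fold change of -1.56 (SE 0.27), GAPDH at -1.18 (SE 0.22), LDHB at -1.05 (SE 0.24) and GPI at -0.57 (SE 0.11). Fatty acid synthesis genes had a lower mean (-0.166, median -0.033, adjusted p = 0.0175, and adjusted p = 0.0987 with an estimated correlation). In this list 5 of 22 passed on their own (7 adjusted over the list alone), among them ELOVL2 (-1.03, SE 0.14), SLC25A1 (-1.04, SE 0.19), ACSL1 (-0.89, SE 0.18) and NR1H3, the oxysterol receptor LXR alpha (-0.41, SE 0.10).

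Plasma protein genes were lower in CS than in T3 (mean -0.746, adjusted p = 1.1e-15; adjusted p = 0.0104 with an estimated correlation), 17 of 30 down and 1 up (19 and 1 adjusted over the list alone). TTR stood at -1.65 (SE 0.25), AMBP at -1.56 (SE 0.28), C8A at -1.20 (SE 0.20) and F9, coagulation factor IX, at -0.82 (SE 0.15). Xenobiotic and steroid metabolism was lower (mean -0.255, adjusted p = 0.00128; adjusted p = 0.0107 with an estimated correlation), with 6 of 21 down and 1 up (8 and 1 adjusted over the list alone). UGT2A1 stood at -0.69 (SE 0.12), CYP2AC1 at -0.83 (SE 0.17), CYP2D6 at -0.72 (SE 0.15) and MGST1 at -0.71 (SE 0.17). Oxidative phosphorylation (mean -0.145, adjusted p = 0.0147; adjusted p = 0.0838 with an estimated correlation) had 6 of 34 down and 1 up (7 and 1 adjusted over the list alone): ATP5H (-0.79, SE 0.15), ATP5B (-0.58, SE 0.13, single spots -1.19 to 0.02) and ATP5G1 (-0.51, SE 0.13), all of ATP synthase, fell, and COX7C of cytochrome c oxidase rose (0.81, SE 0.22). Ribosomal protein genes (mean -0.243, adjusted p = 4e-05; adjusted p = 0.0547 with an estimated correlation) had 4 of 42 down (16 down and 1 up adjusted over the list alone). RPL11 stood at -1.03 (SE 0.23), RPLP2 at -0.76 (SE 0.23), RPL35A at -0.66 (SE 0.18) and RPS12 at -0.57 (SE 0.15). Beside these lists, the per-bird means of bile duct markers (-0.219, adjusted p = 0.0203 over 25 lists) and of pancreas, muscle and adipose carry-over markers (0.0873, adjusted p = 0.0443) differed, each with 6 of 6 CS arrays beyond the T3 mean. The median log2 fold change of the bile duct markers was 0.005, with TM4SF4 at -1.43, so the list did not fall as a whole.

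Leukocyte markers had a lower mean in CS than in T3 (-0.240, median -0.076, adjusted p = 0.0175, and adjusted p = 0.0554 with an estimated correlation). In this list 3 of 15 passed on their own (4 adjusted over the list alone): MARCO of macrophages (-1.10, SE 0.32), the MHC class II chaperone CD74 (-0.85, SE 0.18, single spots -1.97 to 0.05) and CYBB of the phagocyte oxidase (-0.66, SE 0.12). BTK stood at -0.46 (SE 0.14, adjusted p = 0.0514). Among the largest falls by the naming rule, VNN2 (-1.71, SE 0.38), AP1M1 (-1.57), HPGDS, a prostaglandin D synthase (-1.52), and the bile duct marker TM4SF4 (-1.43) fell. DIO1 was higher by 0.30 (SE 0.07, adjusted p = 0.0145; single spots -0.18 to 0.75), while THRA (0.01) and THRB (0.06) did not pass. Of 704 features past the test 231 were higher and 473 lower in CS, with 2297 at an unadjusted p under 0.05. The count was 233 with the values as deposited, 319 without the 4 misplaced arrays, 266 without all 6, 223 after quantile normalization, 282 with equal spread of the arrays (32 up, 250 down) and 269 with only these groups in the fit. Leaving out T3 replicate 5 or CS replicate 5 gave 1073 and 1091. Leaving out CS replicate 4, CS replicate 6, T3 replicate 6 or T3 replicate 2 gave 414, 450, 427 and 435.

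CS+T3 against CS asks what thyroid hormone changed in birds given corticosterone. THRSP rose by 1.65 (SE 0.32, n = 5 and 5, adjusted p = 0.00801), from -0.24 ± 0.71 (SD) in CS to 1.41 ± 0.41. ELOVL2 rose by 1.08 (SE 0.15) and SLC25A1 by 1.07 (SE 0.20). The fatty acid synthesis list had a higher mean (0.218, median 0.059, adjusted p = 0.00762, and adjusted p = 0.0644 with an estimated correlation). In this list 3 of 22 passed on their own (5 adjusted over the list alone). ACSL1 stood at 0.56 (SE 0.19). Oxidative phosphorylation genes rose as a list (mean 0.268, adjusted p = 2.78e-06; adjusted p = 0.00191 with an estimated correlation). In this list 6 of 34 passed on their own (14 up and 1 down adjusted over the list alone): UQCRHL by 1.17 (SE 0.23), ATP5H by 0.84 (SE 0.16), ATP5F1AZ by 0.70 (SE 0.14) and NDUFB6 by 0.50 (SE 0.10). TAT rose by 0.85 (SE 0.15), ATIC, of purine synthesis, by 1.12 (SE 0.23) and FAH, the last enzyme of tyrosine breakdown, by 0.87 (SE 0.20). HPD stood at 0.98 (SE 0.37). The list of these genes, amino acid catabolism, had a mean of 0.166 and a median of 0.071 (adjusted p = 0.0314, and adjusted p = 0.114 with an estimated correlation). Of its members 3 of 29 were up (3 adjusted over the list alone).

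Plasma protein genes were higher in CS+T3 than in CS (mean 0.508, adjusted p = 3.88e-09; adjusted p = 0.045 with an estimated correlation). In this list 3 of 30 passed on their own (17 adjusted over the list alone): F2 by 0.74 (SE 0.14), F9 by 0.80 (SE 0.15) and AMBP by 1.33 (SE 0.28). PLG stood at 0.69 (SE 0.20). Xenobiotic and steroid metabolism rose (mean 0.269, adjusted p = 0.000123; adjusted p = 0.00191 with an estimated correlation). In this list 2 of 21 passed on their own (6 adjusted over the list alone): CYP2D6 by 0.87 (SE 0.16) and CYP2AC1 by 0.71 (SE 0.19). UGT2A1 stood at 0.42 (SE 0.12) and AKR1B10 at 0.46 (SE 0.14). Ribosomal protein genes rose (mean 0.228, adjusted p = 1.3e-05; adjusted p = 0.045 with an estimated correlation). In this list 2 of 42 passed on their own (9 adjusted over the list alone): RPL35A by 0.72 (SE 0.18) and RPS12 by 0.57 (SE 0.15). RPL31 stood at 0.51 (SE 0.15) and RPL11 at 0.75 (SE 0.23). Glycolysis was higher (mean 0.277, median 0.15, adjusted p = 0.015, and adjusted p = 0.0644 with an estimated correlation). In this list 1 of 15 passed on its own (4 adjusted over the list alone): ENO1 by 1.39 (SE 0.28). GAPDH stood at 0.76 (SE 0.23), PGK2 at 0.58 (SE 0.17) and GPI at 0.41 (SE 0.12). Marker lists did not pass the competitive test: erythrocyte markers had a mean of -0.244 (adjusted p = 0.129), leukocyte markers of 0.149 (adjusted p = 0.129), endothelial markers of -0.118 (adjusted p = 0.34) and bile duct markers of 0.127 (median -0.024, adjusted p = 0.823). Per bird, the mean of bile duct markers did pass (0.136, adjusted p = 0.0422 over 25 lists, 4 of 5 CS+T3 arrays above the CS mean). EPB41L5 (1.64) and C1QTNF7 (1.53) rose, CBLB (-1.23), NTRK2 and SIRT2 (-0.86) fell. DIO1 (-0.25), THRA (-0.08) and THRB (-0.14) did not pass.

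Of 246 features past the test between CS+T3 and CS, 209 were higher and 37 lower in CS+T3, with 1964 at an unadjusted p under 0.05. The count was 5 with the values as deposited, 66 without the 4 misplaced arrays, 26 without all 6, 96 after quantile normalization, 194 with equal spread of the arrays (191 up, 3 down), 102 with a block for the replicate number and 490 with array weights. Without CS+T3 replicate 1, 4 or 5 it was 103, 150 and 137. Without CS replicate 4, 5 or 6 it was 106, 675 and 128.

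**Figure D2:**
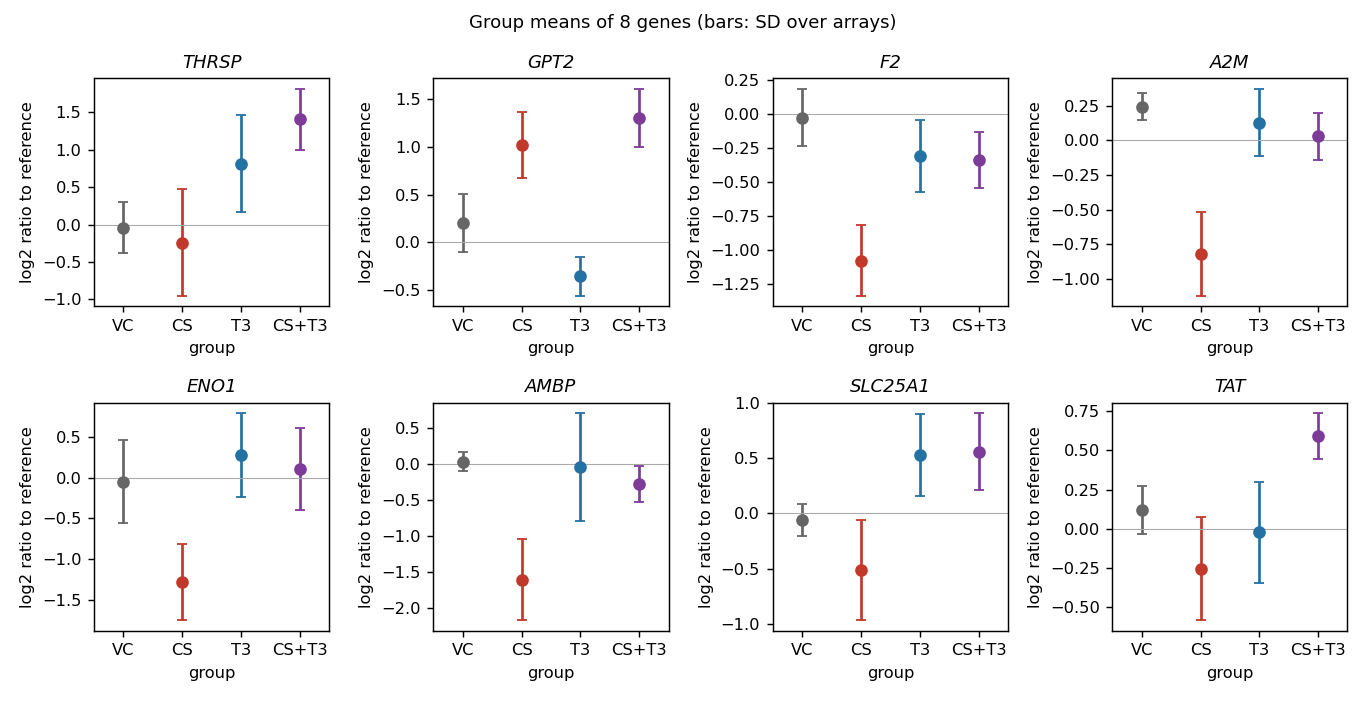
Log2 ratio to the reference pool (y axis) of 8 genes in the 4 groups (x axis); points are group means and bars the SD over arrays. GPT2 is high in both groups given corticosterone (1.02 in CS, 1.30 in CS+T3), while F2 is at -1.08 in CS and -0.34 in CS+T3.

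CS+T3 against T3 asks what corticosterone added in birds given T3. GPT2 rose by 1.66 (SE 0.18, n = 4 and 6, adjusted p = 4.95e-05) and TM2D3 by 1.15 (SE 0.19, n = 5 and 6, adjusted p = 0.00696). GPT2 was named as a member of a list with a call and after its value was seen. These 2 genes and 2 unnamed spots, all up, were the features past the test, with 387 at an unadjusted p under 0.05. The 387 are a smaller share of the 9250 features tested than the 0.05 that unchanged features would give. Amino acid catabolism had a higher mean (0.151, median 0.07, adjusted p = 0.000796, and adjusted p = 0.0355 with an estimated correlation). In this list 1 of 29 passed on its own (2 adjusted over the list alone). The per-bird mean of the list did not pass (difference 0.125, exact permutation p = 0.132, adjusted 0.45 over 25 lists). No other list passed per bird in this comparison. TAT stood at 0.62 (SE 0.15), OAT, an ornithine aminotransferase, at 0.35 (SE 0.15) and PPAT at 0.31 (SE 0.12). Oxidative phosphorylation had a higher mean (0.123, median 0.057, adjusted p = 0.00929, and adjusted p = 0.163 with an estimated correlation). UQCRQ stood at 0.48 (SE 0.15), NDUFS1 at 0.35 (SE 0.14), NDUFC2 at 0.31 (SE 0.12) and NDUFB6 at 0.31 (SE 0.10). Plasma protein genes were lower (mean -0.238, adjusted p = 0.000651; adjusted p = 0.409 with an estimated correlation), 2 down and 1 up adjusted over the list alone, with ORM1 at -1.23 (SE 0.51), TTR at -1.03 (SE 0.25), C8A at -0.69 (SE 0.20) and FGG at 0.62 (SE 0.17). DIO1 (0.05), THRA (-0.07) and THRB (-0.08) did not pass. The count of 4 was 1 with the values as deposited, 0 without all 6 misplaced arrays, 7 with array weights, 8 without CS+T3 replicate 5 and 7 without T3 replicate 6.

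The interaction asks whether the effect of T3 differed with and without corticosterone. F2 differed between the T3 effects by 1.02 (SE 0.20, adjusted p = 0.0492): T3 birds stood at -0.31 and VC birds at -0.03, whereas CS+T3 birds stood at -0.34 and CS birds at -1.08. A2M, the protease inhibitor alpha-2-macroglobulin, differed by 0.96 (SE 0.18, adjusted p = 0.0492), at -0.82 ± 0.30 (SD) in CS and 0.03 ± 0.17 in CS+T3. Plasma protein genes had a positive interaction as a list (mean 0.560, adjusted p = 4.64e-11; adjusted p = 0.0386 with an estimated correlation). In this list 1 of 30 passed on its own (6 adjusted over the list alone). AMBP stood at 1.40 (SE 0.38), PLG at 0.97 (SE 0.27) and F9 at 0.76 (SE 0.21). Xenobiotic and steroid metabolism did too (mean 0.217, adjusted p = 0.00539; adjusted p = 0.0386 with an estimated correlation). CYP2D6 stood at 0.62 (SE 0.22), CYP2C23a at 0.55 (SE 0.25), UGT2A1 at 0.39 (SE 0.16) and CYP3A5 at 0.36 (SE 0.18).

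Amino acid catabolism (mean 0.183, adjusted p = 0.0233; adjusted p = 0.15 with an estimated correlation) had 3 of 29 up adjusted over the list alone, with TAT at 0.99 (SE 0.21, adjusted p = 0.0618), ATIC at 1.19 (SE 0.32), GPT2 at 0.84 (SE 0.24) and FAH at 0.62 (SE 0.27). Oxidative phosphorylation (mean 0.177, adjusted p = 0.00539; adjusted p = 0.0818 with an estimated correlation) had 3 up and 1 down adjusted over the list alone, with UQCRHL at 1.02 (SE 0.32), ATP5H at 0.65 (SE 0.21), NDUFB6 at 0.44 (SE 0.14) and COX7C at -1.28 (SE 0.30). Ribosomal protein genes (mean 0.156, adjusted p = 0.00539; adjusted p = 0.253 with an estimated correlation) included RPL31 at 0.64 (SE 0.20), RPS12 at 0.55 (SE 0.21), RPS23 at 0.37 (SE 0.17) and, in the other direction, RPS4Y1 at -0.50 (SE 0.21). DIO1 (-0.20), THRA (-0.16) and THRB (-0.14) did not pass. The 8 features past the test were all up, 2 named and 6 unnamed, with 906 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0492. The count fell to 0 with the values as deposited, without the 4 or the 6 misplaced arrays, with robust variance estimates, with a replicate block, and in 16 of the 23 fits that left out 1 array. It was 37 with array weights and 36 without CS replicate 5.

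Across 9250 features, the CS and T3 effects against the shared VC arrays correlated at r = 0.083 (covariance 0.00444), where unchanged groups against the same controls gave a mean of 0.502 (range -0.164 to 0.854) and a covariance of 0.0166. With the VC arrays split between them, r was -0.105 and -0.161. For CS and CS+T3, r was 0.279 (simulated mean 0.460; split controls 0.031 and 0.031), and 1 feature rose in both. Independent lists would share 0.049, but these lists share the VC arrays, so that value cannot judge the overlap. For T3 and CS+T3, r was 0.5 (simulated mean 0.480; split controls 0.033 and 0.110). These correlations are across genes, which are not independent replicates.

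**Figure D3:**
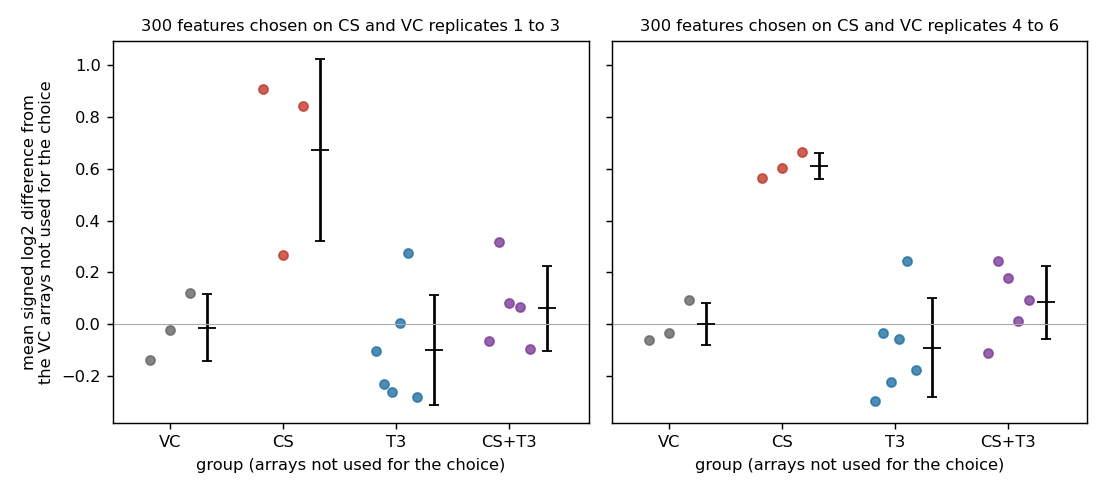
Mean signed log2 difference from VC (y axis) over 300 features chosen on 3 CS and 3 VC arrays, for arrays of the 4 groups (x axis) not used in the choice; points are birds and bars the mean and SD. The CS means are 0.67 and 0.61, and those of CS+T3 are 0.06 and 0.08.

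**Figure D4:**
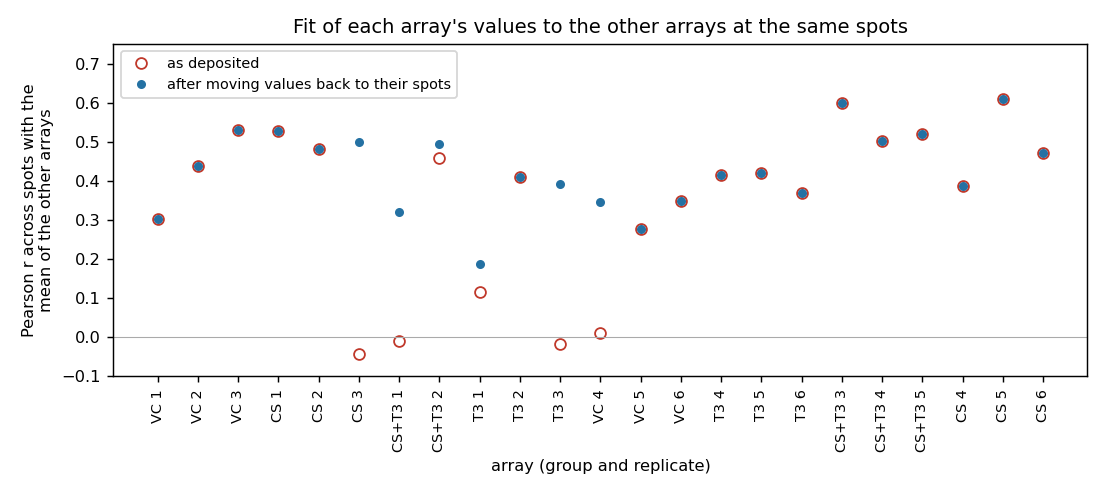
Pearson r across spots of each array with the mean of the other arrays (y axis) for the 23 arrays (x axis), as deposited (open circles) and after values were moved back to their spots (filled circles). On 4 arrays r was -0.042 to 0.012 as deposited and 0.319 to 0.5 afterwards.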

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

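The tests of the plasma protein pattern and of an exchange of CS replicate 5 were chosen after the results had been seen, and the marker and position tests replaced earlier ones on all list members and on GPT2 alone. The other tests in this part were set before.

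Single arrays far from the rest of their group were found in 7 of 187 groups tested by Dixon's criterion, and chance gives about 1 in 20. RPS24 was -0.89 in CS replicate 4 (others -0.54 to -0.35), RPS12 was 0.31 in VC replicate 5 (others -0.43 to -0.24), and CCDC86 was -2.12 in T3 replicate 1 (others -0.55 to -0.06). UGT2A1 was 0.22 in T3 replicate 6 (others -0.01 to 0.02), MGST1 was 0.73 in T3 replicate 2 (others -0.17 to 0.14), and NDUFB6 was 0.52 in CS+T3 replicate 1 (others 0.08 to 0.21). The mean of the plasma protein list was -0.20 in T3 replicate 5 (others 0.25 to 0.47).

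The T3 effect differed with and without CS for F2 (difference 1.02, adjusted p = 0.0492) and A2M (0.96, adjusted p = 0.0492). No feature passed for the interaction in 16 of 23 fits that left out 1 array, nor with the values as deposited, so these 2 calls are not stable. As lists the T3 effect differed for plasma and acute-phase proteins (0.560, adjusted p = 4.64e-11) and xenobiotic and steroid metabolism (0.217, adjusted p = 0.00539), each with adjusted p = 0.0386 with an estimated correlation. At the preset correlation only, 3 more lists passed. They were oxidative phosphorylation (0.177, adjusted p = 0.00539, and adjusted p = 0.0818 with an estimated correlation), amino acid catabolism (0.183, adjusted p = 0.0233, and adjusted p = 0.15 with an estimated correlation) and ribosomal proteins (0.156, adjusted p = 0.00539, and adjusted p = 0.253 with an estimated correlation). These list tests compare genes with other genes, and no per-bird test of list means was run for the interaction.

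Plasma protein genes were lower in CS than in VC. Neither a wider spread of the CS arrays nor any 1 bird accounts for the call of the list. On arrays of equal spread the list mean was -0.699, and the list kept its call in 12 of 12 fits that left out 1 CS or VC array. These fits bear on 1 bird at a time, and the size of the fall varied between birds. The list mean ranged from -0.17 in CS replicate 5 to -0.82 in CS replicate 6. A lower share of hepatocyte RNA is argued against for the whole fall, since the medians of bile acid synthesis (-0.150), fatty acid oxidation (-0.057) and amino acid catabolism (0.019) lay above that of the plasma list (-0.842) by at least 2.52 SD of their members. For part of the fall it stays open: without the member farthest from 0 of each list, marker means were -0.1 for leukocytes (-1.80 in units of its SE over arrays), -0.011 for matrix, 0.001 for bile duct, 0.032 for endothelium and 0.188 for erythrocytes (2.80 in units of its SE). An effect of corticosterone on hepatic transcription, the unstated normalization and a change in RNA content stay open too.

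Features that differed between CS and VC lay nearer VC in CS+T3. Selection of extreme values was tested on arrays not used to choose the features: of 300 features chosen on 3 CS and 3 VC arrays, the mean signed difference from VC was 0.67 in the other CS arrays and 0.06 in CS+T3 (9.0% of it; exact permutation p = 0.0357), and 0.61 and 0.08 when the sets were exchanged (13.7%; exact permutation p = 0.0179, the smallest this design allows). Misplaced values on 6 arrays were tested by leaving those arrays out, where CS+T3 kept -8.6% and 22.2% of the score (exact permutation p = 0.1 each, the smallest possible there). Of the features past the test between CS and VC, 285 of 286 lower ones were higher in CS+T3 than in CS. Of the higher ones, 87 of 91 were lower in CS+T3 than in CS. Both comparisons use the same CS arrays, which favours such opposite signs. Not every response to CS was clearly weaker. GPT2 (1 spot, n = 4 in CS+T3) was at 1.30 in CS+T3 and 1.02 in CS (VC 0.20, T3 -0.36). PSPH differed by 0.30 (SE 0.31, adjusted p = 0.589) between CS+T3 and CS, in the direction of VC. Counteraction of corticosterone by T3 for part of the genes is a candidate biological explanation. A lower exposure to corticosterone stays open as untested, and GPT2, as 1 gene, cannot decide it.

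CS replicate 5 sat apart from the other CS arrays: leaving it out raised the count for CS against VC from 377 to 602, for CS against T3 from 704 to 1091 and for CS+T3 against CS from 246 to 675. Among 300 features chosen without the array placed, it lay 47.9% of the way from T3 to CS (other CS arrays 70.7 to 113.5%), and T3 replicate 5 lay at 45.5% (other T3 arrays -1.6 to 30.5%). An exchange of these birds cannot be told apart from correct labels: the positions lie outside the range of the other group by 1.35 and 1.47 of its SD and outside that of their own by 1.33 and 1.16, and a split with these arrays exchanged gave 1077 features against 704. GPT2 (1.48 in CS replicate 5, -0.49 in T3 replicate 5) stayed with its group and THRSP (0.73 and -0.28) went with an exchange, while PLG (-0.78 and -0.71, other T3 arrays -0.22 to 0.21) left its group in T3 replicate 5 alone and F2 (-0.65 and -0.48, other CS arrays -1.36 to -0.93) in CS replicate 5 alone. A bird given both hormones under a CS label cannot be told apart from a weak response to CS: its position between CS and CS+T3 was 67.2%, above the other CS arrays (-15.7 to 40%) and just under the lowest CS+T3 array (69.9%), so the labels were kept as given.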

How the results depend on the processing

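The values as deposited, the fits without misplaced arrays and the stricter marker spots for the direction were chosen after the data were seen. The count for T3 against VC was 0 under every alternative run. Against counts of 377 (CS against VC), 5 (CS+T3 against VC), 704 (CS against T3), 246 (CS+T3 against CS), 4 (CS+T3 against T3) and 8 (interaction), the alternatives that differed by over 1.5 times gave the following, in that order, with missing places left out. Quantile normalization gave 147 (21 up, 126 down), 3, 223 (50 up, 173 down), 96 for CS+T3 against CS and, for the interaction, 4. Equal spread gave 237 (22 up, 215 down) for CS against VC, 282 (32 up, 250 down, against 231 and 473) for CS against T3 and, for the interaction, 17; for CS+T3 against CS it gave 191 up and 3 down, against 209 and 37. Quantile normalization also gave 3 up and 2 down for CS+T3 against T3. Subtracting medians gave 13 for the interaction. Features on all 23 arrays gave 103, 2, 151, 73 and 1, where fewer (1575) were tested, which lowers counts by construction. Only the compared groups gave 269 for CS against T3. Array weights gave 802 (326 up, 476 down), 31 (24 up, 7 down), 490 (354 up, 136 down) for CS+T3 against CS, 7 for CS+T3 against T3 and 37 for the interaction. Every spot on its own gave 387 for CS+T3 against CS, 7 for CS+T3 against T3 and 0 for the interaction, and a minimum of 2 values or robust variances gave 0 for the interaction too (906 at an unadjusted p under 0.05 in limma). Values as deposited gave 72 (2 up, 70 down), 0, 233, 5, 1 and 0. Without the 4 arrays the counts were 188, 3, 319, 66 and, for the interaction, 0. Without the 6 arrays they were 237, 1, 266, 26, 0 and 0. For all but the filter and the left-out arrays, which had fewer samples, the cause was not tested.

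Leaving out 1 array gave 220 to 602 for CS against VC (220 without CS replicate 4, 248 without VC replicate 2, 602 without CS replicate 5), 0 to 0 for T3 against VC, 3 to 6 for CS+T3 against VC (3 without CS+T3 replicate 1), 414 to 1091 for CS against T3, 103 to 675 for CS+T3 against CS, 4 to 8 for CS+T3 against T3, 0 to 36 for the interaction (0 in 16 of 23, 16 without T3 replicate 6, 36 without CS replicate 5) and 28 to 37 for list shifts. List shifts, 32 at the preset correlation, were 16 with an estimated correlation, 16 on features of all 23 arrays and 20 as deposited. Named genes past the test lost their call in 137 of 856 fits with another setting fixed before the data were seen, in 198 of 1097 fits that left out 1 array, and in 156 of 270 with the values as deposited or without the 4 or 6 arrays. Lists lost theirs in 42 of 344, 28 of 423 and 26 of 96. Named genes short of the test passed in 30 of 819, 30 of 1279 and 0 of 269 (limma). The correlation of CS and T3 effects, 0.083, turned to -0.105 and -0.161 with split controls, where no VC array is shared. The share of positive marker values, 56.7% (59.6% of all spots), was 75% and 100% in stricter sets (63.5% and 62.3% of all spots), which settled no direction; THRSP, FKBP5 and TAT in CS+T3 against VC (1.45, 0.47 and 0.47, none past the test) had the signs of the assumed one.

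Replicate numbers are shared by the groups but do not pair the arrays: deviations from group means correlated at a median of -0.026 in 33 pairs with the same number (-0.407 to 0.324; 9 above 0.1), and 2 of 23 arrays correlated best with their own number. A replicate block gave 280 for CS against VC, 0 for T3 against VC, 4 for CS+T3 against VC, 526 for CS against T3, 102 for CS+T3 against CS, 3 for CS+T3 against T3, 0 for the interaction and 32 list shifts. Signal over background could not be examined, since the files hold ratios only.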

Other observations

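For 15 lists without a call by the competitive test in any comparison, the values are those of CS against VC. Lipid droplets and lipoproteins had a mean log2 fold change of -0.151 (adjusted p = 0.205), fatty acid oxidation and ketone bodies -0.028, cholesterol synthesis 0.067, and gluconeogenesis and glycogen -0.042. Thyroid hormone response and metabolism had a mean of -0.058 and a median of 0.075, and its test pointed up (adjusted p = 0.862). The growth hormone and IGF axis stood at 0.041, the tricarboxylic acid cycle at -0.081 with a median of 0.053, endoplasmic reticulum folding and heat shock at -0.109, the proteasome at -0.025 with a median of 0.003 and the cell cycle at 0.105. Among marker lists, erythrocytes stood at 0.268 (adjusted p = 0.131), stellate cells and matrix at 0.011, endothelium at 0.076 with a median of -0.014, bile duct at -0.161 with a median of 0.005, and pancreas, muscle and adipose carry-over at 0.010.

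The mean of a list per bird, tested by exact permutation and adjusted over 25 lists, compares birds and not a list with other genes, and it passed for some of these lists. In CS against VC 7 of 25 lists passed, among them lipid droplets and lipoproteins (difference -0.169), erythrocytes (0.262) and bile duct (-0.173), each with adjusted p = 0.0386 and 6 of 6 CS arrays beyond the VC mean. Without TM4SF4, the mean log2 fold change of the bile duct list in CS against VC was 0.001. Glycolysis passed there as well (-0.226, adjusted p = 0.0386). In CS against T3 12 passed, among them lipid droplets (-0.219), the growth hormone axis (0.157) and bile duct (-0.219), each with adjusted p = 0.0203, the cell cycle (0.175, adjusted p = 0.027), carry-over (0.0873, adjusted p = 0.0443) and endoplasmic reticulum folding (-0.0947, adjusted p = 0.045). In CS+T3 against CS 9 passed, among them lipid droplets (0.176, adjusted p = 0.0386) and bile duct (0.136, adjusted p = 0.0422). The median log2 fold change of the bile duct list was 0.005 in CS against T3 and -0.024 in CS+T3 against CS. None of 25 passed in T3 against VC, CS+T3 against VC or CS+T3 against T3.

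For T3 against VC, a noisy T3 replicate 1 and too few arrays were set down as explanations of the count of 0 and run, and were then taken out of the set of weighed patterns after their results were seen. Without T3 replicate 1 the count stayed at 0 (limma; 440 features had an unadjusted p under 0.05 with it, a share under 0.05 of the 9250 tested). In simulated data with noise independent between features and equal on all arrays, 45% of changes of 0.5 and 93% of changes of 1 were recovered.

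Chance as the source of the counts was tested with 100 splits of the same arrays for each of 6 comparisons, the real one included, and for the interaction with reordered residuals in their place. These tests were set before their results were seen, except that the reordering was corrected after its result was seen. For CS against VC 1 split gave as many features (377; highest other 253), for CS+T3 against VC 1 (5; highest other 1), for CS+T3 against CS 2 (246; highest other 315) and for CS against T3 3 (704; highest other 1077). Each of these is under the limit of 5 of 100 set beforehand, which was not adjusted over the comparisons. For the last 2, other splits gave more features than the real one. The count of 5 for CS+T3 against VC was 0 with the values as deposited and 1 without the 6 arrays. For the interaction 1 of 100 gave as many (8; highest other 0), which is under that limit for that 1 fit only: its smallest adjusted p was 0.0492, and the count was 0 in 16 of 23 fits that left out 1 array, with robust variances, with a replicate block and with a minimum of 2 values per group. For T3 against VC the real count was 0, which any split reaches, so all 100 gave as many by construction and the splits decide nothing there (highest other 1). For CS+T3 against T3, 5 splits gave as many as the real one (4, highest other 17), so chance cannot be excluded for that comparison. The split with 1077 features exchanged CS replicate 5 and T3 replicate 5, and that with 315 exchanged CS replicate 5 and CS+T3 replicate 2, which points to a structure of the samples that the groups do not describe.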
